A study of Mus musculus with 7 samples.

How the data were processed

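RNA was sequenced from 7 mouse cultures: 1 library of V6.5, an established mouse embryonic stem cell (ESC) line, and 6 libraries of induced pluripotent stem cell (iPSC) colonies. Per the labels' design text, male mice were immunized with SRBC for 9 days, and splenic germinal center (GC) B cells, the B cells that mutate and select their antibody genes, were sorted as B220+ CD38- Fas+. Cells were taken either in bulk or by a Myc-GFP reporter that marks GC B cells activated by T follicular helper cells. The sorted cells spent 6 days with cytokines on mouse embryonic fibroblasts (MEF), a feeder layer, and were reprogrammed for 10 days with doxycycline (Dox), the drug that switches on the reprogramming genes. After 4 days without Dox, 3 colonies per source were picked, passaged 1 time on gelatin and pre-plated for 45 min to remove feeders. Colonies titled GC are called GC colonies here, and those titled M are called M colonies. The titles do not spell out M; it is read as the Myc-GFP source, because the design names only that source beside bulk GC B cells. Per the labels' growth protocol, cells were kept in KO-DMEM with serum and LIF, a cytokine that sustains mouse pluripotency. The labels give neither the donor mouse of each colony nor a batch or date.

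The values analysed are raw counts per Ensembl gene deposited by the authors, whole numbers without normalization. Per the submitters' processing notes, reads were aligned with STAR 2.7.10a to mm10 (GRCm38) and counted with featureCounts 2.0.6, and DESeq2 (version not given in the sources used here) is named as a later step. The labels disagree on the library: the design text gives non-stranded poly-A libraries read as 150-base pairs of ends on a NovaSeq X Plus, whereas the sample protocol gives a directional kit and a NovaSeq 6000. The strand setting of the count is not given in the sources used here, so a gene and its antisense neighbour may share counts. Counts per gene also do not separate RNA of the Dox-driven reprogramming genes from that of the cells' own copies, and this was not tested. Among counts of 1 to 49, between 68.5% and 72.2% were even in each library, against 49.5% to 50.9% at 1000 or more. That excess is what counting the 2 mates of a pair one by one would give, which was not tested, and the counts may then overstate the number of fragments. Totals ran from 31139508 counts (ESC) to 35728921 counts (GC colony 1). A count of 0 allows up to 3 counts, which is 0.0840 to 0.0963 CPM (counts scaled by library size) by library. This floor covers counting error only and takes counts as independent, which mates of a pair are not. The intervals given below are for shares of genes and take genes as independent, which they are not.

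Gene names, types and positions came from GENCODE release M21 on GRCm38. Of 54838 genes in the table, 54809 matched it; the 29 others held at most 465 counts in a library. Another 727 annotated genes were not analysed here. No mitochondrial counts were in the table. Groups came from the sample titles. M colonies were compared with GC colonies in a fit of the 6 iPSC libraries, and iPSC colonies with ESC in a fit of all 7 libraries, with the mean of both colony groups set against the ESC library. GC colonies and M colonies were also each compared with ESC in the 7-library fit. Genes were filtered with filterByExpr, which left 18166 genes for 6 libraries and 20502 for 7, scaled by TMM and tested two-sided with the quasi-likelihood test of edgeR 4.0.16. Every "edgeR adjusted p" is a Benjamini-Hochberg value from that test, with a threshold of 0.05. A standard error (SE) of a log2 change is its size over the square root of its F statistic. Group means are TMM-scaled CPM with the SD over colonies, from the fit of the comparison at hand. With 1 ESC library, the spread came from the colonies alone, and the lone library was assumed to vary like them. The labels do not say that colonies came from separate mice, so each p measures spread among these colonies only, and source cell and donor cannot be told apart.

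There were 21 gene lists: naive and general pluripotency, primed and formative pluripotency, 2-cell-like state, B cell identity, germinal center B cell, Myc target, fibroblast (feeder) marker, Dlk1-Dio3 imprinted cluster, other imprinted gene, mesoderm and endoderm, neuroectoderm, primitive endoderm, trophoblast, methylation-sensitive germline, Y-linked, p53 target, integrated stress response, glycolysis and hypoxia, cholesterol synthesis, interferon response, and immediate early. Each list with at least 3 measured members was tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the lists ("camera adjusted p"). Camera was repeated with an estimated correlation, and fry was run as another test. Groups, tests, lists, the rule for named genes and most of the other settings were fixed before the data were examined.

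The rule named a fixed set of genes in every case, of which these are reported here: Pou5f1, Sox2, Klf4, Myc, Nanog, Lin28a, Esrrb, Zfp42, Meg3, Rian, Mirg, H19, Pax5, Bcl6, Fas, Cd38, Col1a1 and Col1a2. For M against GC it added, among called genes with no overlap between groups, a mean of at least 1 CPM and no clone-style name, the 15 with the largest rise and the 15 with the largest fall. For iPSC against ESC it added the 12 with the largest rise and the 12 with the largest fall whose ESC value lay outside the range of the 6 colonies. Of each list it took up to 4 called members with the smallest p, or, with none called, 1 or 2 of the most abundant. Further called members are named in most cases where 5 or fewer members of a list moved in a direction; these were chosen after their values were seen. A few genes that the rule names, or that a list's count includes, are not reported by name here.

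The distance of a colony to ESC was the root mean square difference in log2 CPM (prior count 2) over 20502 genes, compared between groups by an exact permutation test. Chromosome levels were medians of the log2 ratio of each library to the mean of the 6 others. The pipeline was tested on simulated data with 200 changed genes. In M against GC it recovered 30 of 50 genes changed 1.5-fold, 44 of 50 at 2-fold, 49 of 50 at 4-fold and 50 of 50 at 8-fold, with 7 false calls. In iPSC against ESC it recovered 24, 37, 46 and 48 of 50 at the same folds, with 11 false calls. Both simulations drew genes independently, and the simulated ESC library was given the spread of the colonies. Their false calls therefore do not give the error rate of the real calls. The other settings fixed in advance were RLE scaling, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, each colony left out in turn, the colony number as a block, all 7 libraries in the M against GC fit, a test against a fold of 1.5, and for the distance a prior count of 0.5 and a mean CPM of at least 10. Added after the data were seen were halved counts, M colonies 2 and 3 left out (which leaves 1 M library, with no spread of its own), chromosomes 8 and Y left out, protein-coding genes alone, and chromosome levels under RLE or a mean CPM of at least 10. R 4.3.3, Python 3.11.15 and matplotlib 3.10.9 were used.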

Results

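Poly-A RNA was sequenced from 7 mouse cultures: 1 library of the ESC line V6.5, 3 colonies of iPSCs derived from bulk GC B cells (GC colonies) and 3 colonies read as derived from GC B cells sorted by a Myc-GFP reporter (M colonies). The deposited table held 31139508 counts for ESC. It held 35728921, 32272377 and 31612440 counts for GC colonies 1 to 3, and 32803758, 33173123 and 31505623 counts for M colonies 1 to 3. Between 23609 (ESC) and 25400 (GC colony 1) genes were detected per library. Across genes, Pearson correlations of log2 CPM within a colony group ran from 0.979 to 0.986, those between GC and M colonies from 0.974 to 0.980, and those with ESC from 0.961 to 0.969; genes are not independent replicates. The first principal component held 31.8% of the variance and set ESC apart, and the second held 21.7% and set M colonies apart from GC colonies.

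M colonies were compared with GC colonies to ask whether the sorted B cell state left a difference in the reprogrammed cells. M colonies had less RNA of 23 of 36 genes of the 2-cell-like state, a program of the early embryo that also appears in rare cultured stem cells. They had more RNA of 8 of 24 primitive endoderm genes, which mark an extraembryonic lineage, and of 9 of 18 immediate early genes, which respond within minutes to growth factors or stress. The list test camera called these 3 lists, and called none of them with an estimated correlation (adjusted p from 0.135 to 0.183). They also had more of the keratin genes Krt8 and Krt18, which code for filaments of simple epithelia, and of Peg10, a paternally expressed imprinted gene needed for the placenta. Pou5f1, which encodes the central pluripotency factor Oct4, was 376.9 ± 3.5 CPM (SD, n = 3) in GC colonies and 494.5 ± 11.9 CPM (SD, n = 3) in M colonies. Of the 38 naive and general pluripotency genes as a whole, 4 rose and 4 fell, and camera did not call the list. The counts do not separate RNA of the Dox-driven reprogramming genes from that of the cells' own copies. Of the B cell and GC B cell genes, Cd37 and Icam1 passed the edgeR test, both lower in M colonies. Both stood higher in the ESC library than in any colony.

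In this comparison 721 of 18166 tested genes passed the edgeR threshold, of which 308 rose and 413 fell in M colonies. Of the 721, 205 changed by at least 1 on the log2 scale and 625 were protein-coding. Their 3 M values lay wholly above or below the 3 GC values in 716 of the 721, against 22.1% of all tested genes and 10% by chance. Passing the test largely brings this about, so it is no separate support. M colonies 2 and 3 had 0 counts for 8 Y-linked genes, described with the chromosome levels, and without both colonies, a setting chosen after the data were seen, 373 genes passed, including 252 of the 721. That setting, here and for the lists of this comparison, leaves 1 M library, so its spread comes from the GC colonies alone and its calls separate M colony 1 from them, not M from GC colonies. Leaving out GC colony 1, GC colony 2 or M colony 3 left 412, 244 or 270 genes. Of 68 named genes called here, 33 stayed past the threshold when any 1 colony was left out, and 31 were lost without GC colony 2.

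Of 36 measured members of the 2-cell-like list, 23 fell in M colonies, 0 rose and 13 did not pass, and 33 fell when adjusted over the list alone. The median log2 change was -0.87, with a camera adjusted p = 1.82e-36 (adjusted p = 0.135 with an estimated correlation). Tmem92 fell from 31.1 ± 3.1 to 14.2 ± 2.1 CPM (SD, n = 3 each). Gm2016 fell from 36.1 ± 3.3 to 15.2 ± 3.1 CPM. Tdpoz4 (ENSMUSG00000060256, chromosome 3 from 93796398 to 93797510) had the largest fall of the list, by 3.16 ± 0.27 (SE) on the log2 scale, with an edgeR adjusted p = 3.69e-05. Without M colonies 2 and 3, 29 of 38 measured members fell and 1 rose. Many of these genes lie in families of near-identical copies, so counts of single members are uncertain.

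Of 24 primitive endoderm genes, 8 rose in M colonies, 0 fell and 16 did not pass, and 20 rose when adjusted over the list alone. Camera gave an adjusted p of 1.77e-15 (adjusted p = 0.183 with an estimated correlation), and fry did not call the list (adjusted p = 0.104). Cubn, an endocytic receptor, rose from 150.2 ± 22.8 to 314.5 ± 88.5 CPM (SD, n = 3 each). Dab2, an adaptor for such receptors, rose from 130.6 ± 17.1 to 241.9 ± 58.3 CPM. Foxq1, a forkhead transcription factor, rose from 8.19 ± 0.66 to 18.2 ± 3.7 CPM. Without GC colony 2 or M colony 3 the number that rose was 4, without M colony 2 it was 19, and without M colonies 2 and 3 it was 17. Fibroblast markers, which would enter with leftover feeders, were measured beside this group: of 36, 0 passed edgeR, DESeq2 or limma-voom, and 6 were higher at an unadjusted p under 0.05. Their camera adjusted p was 0.0254 upward (adjusted p = 0.615 with an estimated correlation). That call ended without GC colony 1 (0.175) and without M colony 1 (0.840), held without GC colony 2 (0.0376), and had a smaller adjusted p without GC colony 3 (4.24e-04, with 4 genes risen), M colony 2 (0.0192, with 2 risen), M colony 3 (4.04e-05, with 0 risen) or M colonies 2 and 3 (2.68e-08, with 1 risen). Fn1, the most abundant of them, was 1655 ± 224 CPM in GC colonies and 1656 ± 107 CPM in M colonies, with a sign that flipped with the low-count filter, and Sparc, which is also in the primitive endoderm list, was 1153 ± 88 and 1417 ± 329 CPM.

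Of 18 immediate early genes, 9 rose in M colonies, 0 fell and 9 did not pass, and 17 rose when adjusted over the list alone. By camera the adjusted p was 5.57e-15 (adjusted p = 0.135 with an estimated correlation). Jun rose from 226.9 ± 9.1 to 303.9 ± 21.6 CPM (SD, n = 3 each). Fosb rose from 406.9 ± 27.4 to 528.4 ± 33.0 CPM, a call lost without GC colony 2 or M colony 3 (edgeR adjusted p up to 0.0661). The number that rose was 5 without GC colony 1, 1 without GC colony 2, 6 without M colony 2, 1 without M colony 3 and 2 without M colonies 2 and 3.

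Of 38 naive and general pluripotency genes, 4 rose (Pou5f1, Klf4, Mybl2 and Dnmt3l), 4 fell (Fbxo15, Tcl1, Dppa2 and Klf2) and 30 did not pass, while 5 rose and 13 fell when adjusted over the list alone. The camera test did not call the list (adjusted p = 0.158, and adjusted p = 0.617 with an estimated correlation). Pou5f1 (ENSMUSG00000024406, chromosome 17 from 35506018 to 35510772) rose by 0.39 ± 0.05 (SE) on the log2 scale, with an edgeR adjusted p = 0.00120. Fbxo15, a gene switched on by Oct4, fell from 226.1 ± 10.7 to 132.3 ± 15.5 CPM (SD, n = 3 each). Klf4, a reprogramming factor, rose by 0.40 ± 0.07 (SE), a call lost without GC colony 2 (edgeR adjusted p = 0.0575). Nanog was 488.0 ± 6.4 and 412.7 ± 41.6 CPM, Sox2 421.6 ± 7.9 and 375.5 ± 27.7 CPM, Zfp42 469.6 ± 7.6 and 325.7 ± 103.7 CPM, and Myc 26.0 ± 3.3 and 33.8 ± 1.8 CPM in GC and M colonies, without passing the test. Lin28a (364.5 ± 6.8 and 373.4 ± 15.4 CPM) and Esrrb (399.0 ± 26.1 and 413.2 ± 48.0 CPM) did not pass either. The list was called downward without M colony 2 (camera adjusted p = 0.0233) and without M colonies 2 and 3 (0.0415). Over the leave-outs 1 to 3 genes rose and 2 to 7 fell, with 1 and 2 without GC colony 2, 2 and 2 without GC colony 1 or M colony 3, 2 and 5 without M colony 1 or M colony 2, and 3 and 7 without GC colony 3.

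Of 25 primed and formative pluripotency genes, which mark the state after implantation, 4 rose (Krt18, Sox3, Etv4 and Car4), 2 fell (Otx2 and Lefty1) and 19 did not pass, while 9 rose and 3 fell when adjusted over the list alone. For the list as a whole, the camera adjusted p was 0.00654 upward (adjusted p = 0.135 with an estimated correlation). Krt18 rose from 158.0 ± 11.6 to 265.3 ± 35.8 CPM (SD, n = 3 each). Otx2, a transcription factor of the formative state, moved against the list, from 54.0 ± 2.3 to 29.9 ± 4.7 CPM. Without GC colony 2 or M colony 3, 2 rose and 1 fell, and 1 fell without GC colony 1 or M colony 2.

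Of 16 trophoblast genes 3 rose (Krt8, Krt7 and Krt19), 0 fell and 13 did not pass, with 3 risen when adjusted over the list alone. The camera adjusted p was 0.0254 (adjusted p = 0.149 with an estimated correlation). Krt8 (ENSMUSG00000049382, chromosome 15 from 101996698 to 102004482) rose from 222.5 ± 13.8 to 371.2 ± 32.0 CPM (SD, n = 3 each), by 0.74 ± 0.07 (SE) on the log2 scale, with an edgeR adjusted p = 1.29e-04. The list call ended without GC colony 3 (0.0925) and without M colonies 2 and 3 (0.0660), 2 genes rose without GC colony 3 or M colony 2, and 1 rose without GC colony 2 or M colony 3. Of 26 mesoderm and endoderm genes 3 rose (Eomes, Lhx1 and Sp5), 0 fell and 23 did not pass, while 7 rose and 1 fell when adjusted over the list alone. Camera gave an adjusted p of 0.00106 (adjusted p = 0.135 with an estimated correlation). Eomes, a T-box factor of gastrulation, rose from 10.4 ± 0.4 to 18.6 ± 2.1 CPM. The number that rose was 2 without GC colony 2 or GC colony 3 and 1 without GC colony 1, M colony 1 or M colony 3, while without M colony 2, 4 rose and 1 fell. Sp5 was lost in each of the 6 leave-outs (edgeR adjusted p up to 0.176).

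Of 49 other imprinted genes 6 rose, 0 fell and 43 did not pass, while 10 rose and 2 fell when adjusted over the list alone. By camera the adjusted p was 0.0299 (adjusted p = 0.149 with an estimated correlation). Peg10 (ENSMUSG00000092035, chromosome 6 from 4747306 to 4760517) rose from 356.4 ± 21.5 to 731.4 ± 100.04 CPM (SD, n = 3 each), by 1.04 ± 0.09 (SE) on the log2 scale, with an edgeR adjusted p = 3.69e-05. Nnat, a neuronal imprinted gene, rose from 14.6 ± 0.8 to 23.6 ± 3.0 CPM. H19 was 135.0 ± 23.6 and 171.2 ± 35.4 CPM and did not pass. The list call ended without GC colony 1 (camera adjusted p = 0.0666), when 3 genes rose, and 2 rose without GC colony 2 or M colony 3, while without GC colony 3, 4 rose and 1 fell. Of 6 genes of the Dlk1-Dio3 cluster, whose silencing is a known fault of some iPSC lines, 0 passed edgeR, DESeq2 or limma-voom, 3 were higher at an unadjusted p under 0.05, and 2 rose when adjusted over the list alone. For the list as a whole, the camera adjusted p was 0.0180 upward (adjusted p = 0.149 with an estimated correlation), and 1 gene rose without M colony 2. Rian was 26.8 ± 0.7 CPM in GC colonies and 42.1 ± 13.8 CPM in M colonies, Meg3 was 32.8 ± 5.4 and 39.4 ± 5.4 CPM, and Mirg was 0.592 ± 0.275 and 1.21 ± 0.39 CPM.

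**Figure D1:**
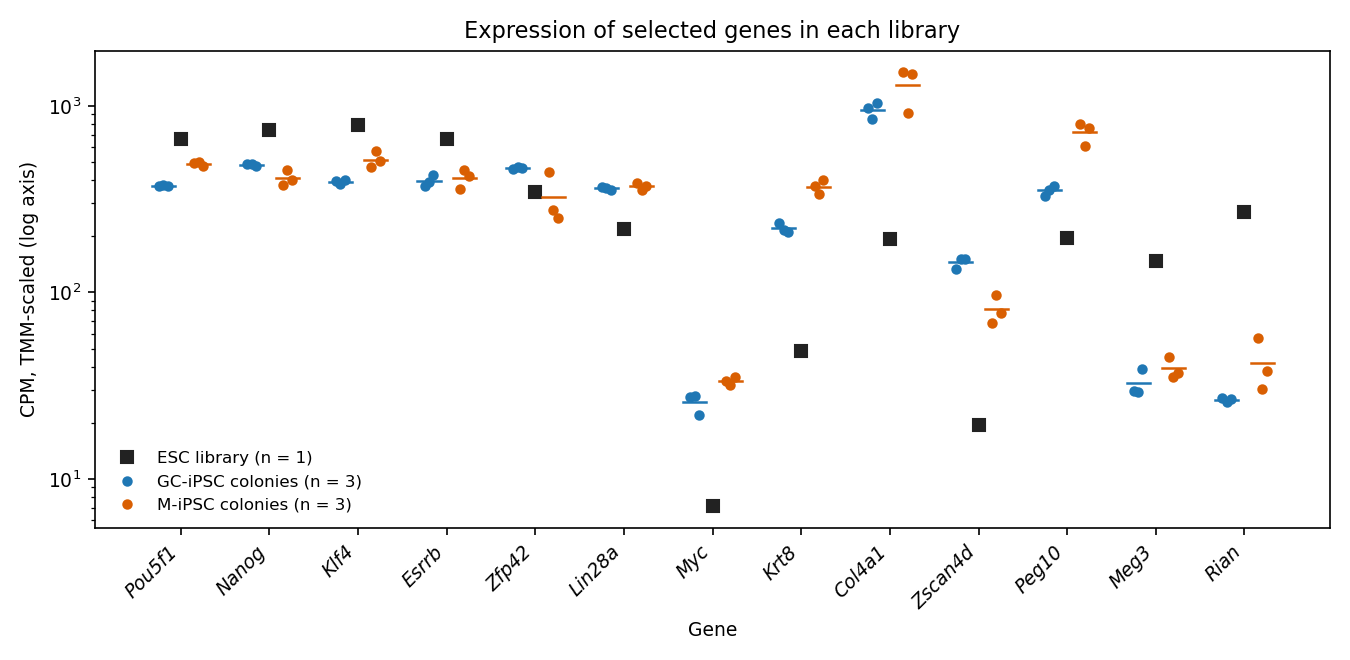
TMM-scaled CPM on a log axis of 13 genes in each library: black squares are the ESC library (n = 1), blue points GC colonies (n = 3) and orange points M colonies (n = 3), and bars are group means. Pou5f1, Krt8 and Peg10 lie higher in M than in GC colonies, whereas Meg3 and Rian lie far below ESC in both.

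B cell genes were looked at as traces of the donor cells. Of 18 measured B cell identity genes 1 fell (Cd37), 0 rose and 17 did not pass, with 1 fallen when adjusted over the list alone. Cd37, a B cell surface tetraspanin, fell from 14.6 ± 0.7 to 7.65 ± 0.93 CPM (SD, n = 3 each). The camera adjusted p was 0.0412 downward (adjusted p = 0.302 with an estimated correlation), and the call ended without GC colony 1 (0.102), GC colony 3 (0.0566) or M colony 1 (0.389) and with the colony number as a block (0.0527). Of 20 GC B cell genes 1 fell (Icam1, from 87.6 ± 3.7 to 64.0 ± 3.3 CPM), 0 rose and 19 did not pass, with 1 fallen when adjusted over the list alone. The list was not called (camera adjusted p = 0.859, and adjusted p = 0.905 with an estimated correlation), and its median (-0.017) and mean (0.016) differed in sign. Pax5, the B cell master regulator, was 0.627 ± 0.157 CPM in GC and 0.264 ± 0.295 CPM in M colonies. Bcl6, the GC regulator, was 4.21 ± 0.85 and 4.81 ± 0.80 CPM. The sort markers Fas (1.55 ± 0.16 and 1.90 ± 0.37 CPM) and Cd38 (8.76 ± 0.69 and 11.0 ± 0.4 CPM) did not pass. The ESC library, not derived from B cells, held more Cd37 (18.9 CPM) and Icam1 (98.0 CPM) than any colony. Their levels in GC colonies therefore do not by themselves mark a trace of the donor cells.

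Of 69 Myc target genes, measured because the reporter follows Myc, 0 passed in edgeR, in DESeq2, in limma-voom or when adjusted over the list alone, and 2 were higher at an unadjusted p under 0.05. Camera did not call the list (adjusted p = 0.320, and adjusted p = 0.754 with an estimated correlation), except without M colonies 2 and 3 (0.0367 upward), and 1 gene rose without GC colony 3. Npm1, a nucleolar chaperone, was 2769 ± 55 CPM in GC colonies and 2677 ± 45 CPM in M colonies (SD, n = 3 each). Of 37 interferon response genes 2 fell (Ifitm1 and Zbp1), 0 rose and 35 did not pass, with 4 fallen when adjusted over the list alone. Camera gave an adjusted p of 0.0113 downward (adjusted p = 0.149 with an estimated correlation), a call that ended without M colonies 2 and 3 (0.0724). Ifitm1, a viral entry inhibitor, fell from 82.8 ± 7.0 to 52.6 ± 11.2 CPM, a call lost without GC colony 2 or M colony 3 (edgeR adjusted p up to 0.0637). The number that fell was 0 without GC colony 2, 1 without GC colony 1, M colony 2 or M colony 3, and 3 without M colony 1, when 1 also rose.

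Among the named genes the largest rise in M colonies was in Pnp2, a purine nucleoside phosphorylase (ENSMUSG00000068417, chromosome 14 from 50955992 to 50964749). Pnp2 rose from 1.09 ± 0.42 to 6.73 ± 1.12 CPM (SD, n = 3 each), by 2.61 ± 0.27 (SE) on the log2 scale, with an edgeR adjusted p = 2.36e-04. Tagap1 rose from 6.15 ± 0.35 to 21.7 ± 2.3 CPM, Irs4, a signalling adaptor, from 3.83 ± 1.16 to 11.4 ± 2.7 CPM, and Dkk1, a secreted Wnt inhibitor, from 2.62 ± 0.50 to 7.26 ± 1.87 CPM. The rest of the 15 largest rises ran from 1.37 (Muc13) to 2.39 (Prr18) on the log2 scale. Prr18 stayed called in 6 of 6 leave-outs. Muc13 stayed called in 2 of 6 (edgeR adjusted p up to 0.1465), and limma-voom did not call it. The largest fall was in Rps3a3, a processed pseudogene of a ribosomal protein gene (ENSMUSG00000059751, chromosome 13 from 108670603 to 108671397). Rps3a3 went from 303.9 ± 13.5 to 18.3 ± 3.8 CPM, a fall of -4.05 ± 0.12 (SE) on the log2 scale, with an edgeR adjusted p = 8.57e-10. Its reads can be shared with near-identical copies. Mid1, a microtubule-bound ubiquitin ligase (ENSMUSG00000035299, chromosome X from 169685199 to 170005736), went from 29.0 ± 1.3 to 2.22 ± 0.93 CPM, with an edgeR adjusted p = 5.67e-07. Mobp, a myelin gene, fell from 9.94 ± 0.21 to 2.87 ± 0.52 CPM, and Dpys, an enzyme of pyrimidine breakdown, from 14.1 ± 0.8 to 4.68 ± 2.28 CPM. Apart from Tdpoz4, the rest of the 15 largest falls ran from -1.47 (D13Ertd608e) to -2.45 (Guca1b) on the log2 scale. D13Ertd608e stayed called in 5 of 6 leave-outs and Guca1b in 2 of 6 (edgeR adjusted p up to 0.1301).

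iPSC colonies were compared with the ESC library to ask how far the reprogrammed cells resembled an established pluripotent line. The colonies had more RNA than ESC of 33 of 38 genes of the 2-cell-like state, 21 of 24 of primitive endoderm, 9 of 16 of trophoblast (1 fell) and 24 of 36 of fibroblasts. Camera called these 4 lists, and called none of them with an estimated correlation (adjusted p from 0.0701 to 0.122). The colonies had less of the imprinted transcripts Meg3, Rian and Mirg. Rian, a noncoding RNA of the Dlk1-Dio3 cluster, was 269.9 CPM in ESC and 34.2 ± 11.99 CPM (SD, n = 6) in the colonies. Col4a1, a basement membrane collagen of the primitive endoderm list, was 193.6 CPM in ESC and 1129 ± 293 CPM (SD, n = 6) in the colonies. Of 38 naive and general pluripotency genes 21 were lower in the colonies (camera adjusted p = 0.110 with an estimated correlation), Pou5f1 at 432.2 ± 64.8 CPM (SD, n = 6) against 661.0 CPM.

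Of 20502 tested genes 3344 passed edgeR, 1795 higher and 1549 lower in the colonies, and 1296 changed by at least 1 on the log2 scale. ESC lay outside the range of the 6 colonies for 3326 of them, against 51.4% of tested genes and 28.6% by chance. This too largely follows from passing the test. With 1 ESC library a call separates that library from these colonies, not ESC lines from iPSC lines. Chromosome 8 genes stood higher as a whole in the ESC library (median log2 ratio 0.268 to the other libraries), and without chromosomes 8 and Y 3041 genes passed. Limma-voom called more genes lower (1584) than higher (1194) in the colonies. All 100 named genes called here stayed past the threshold with any 1 colony left out. Apart from the fixed set, these genes were named for large changes or small p, and the ESC library itself cannot be left out. Limma-voom did not call some of them, Rbbp8nl and Irf4 among them.

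Of 38 naive and general pluripotency genes 21 fell, 5 rose (Lin28a and Dnmt3l among them) and 12 did not pass, while 22 fell and 6 rose when adjusted over the list alone. By camera the adjusted p was 1.84e-07 downward (adjusted p = 0.110 with an estimated correlation). Tcl1, a coactivator of the kinase Akt, fell from 116.4 CPM in ESC to 37.0 ± 8.2 CPM (SD, n = 6), by 1.68 ± 0.10 (SE) on the log2 scale, with an edgeR adjusted p = 4.39e-07. Nanog fell from 740.2 to 446.6 ± 48.5 CPM, Klf4 from 788.2 to 453.9 ± 76.0 CPM, Esrrb from 666.4 to 402.8 ± 35.5 CPM and Sox2 from 506.2 to 395.3 ± 30.8 CPM. Lin28a, which blocks let-7 maturation, rose from 217.5 to 366.0 ± 11.5 CPM. Zfp42 was 345.9 and 394.4 ± 101.7 CPM and did not pass. Without chromosomes 8 and Y, 20 of 36 fell, since Klf2 and Zfp42 lie on chromosome 8. Of 25 primed and formative genes 15 rose, 3 fell (Zic2, Tead2 and Zic5) and 7 did not pass, while 17 rose and 3 fell when adjusted over the list alone. For the list as a whole, the camera adjusted p was 2.58e-07 (adjusted p = 0.0701 with an estimated correlation). Krt18 rose from 23.7 to 210.0 ± 62.9 CPM, and Dnmt3b, a DNA methyltransferase, from 105.4 to 329.1 ± 53.5 CPM.

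Of 38 2-cell-like genes 33 rose, 0 fell and 5 did not pass, with 35 risen when adjusted over the list alone. The camera adjusted p was 5.38e-25 (adjusted p = 0.0922 with an estimated correlation). Zscan4d, which marks rare 2-cell-like cells, was 19.6 CPM in ESC and 113.1 ± 36.8 CPM (SD, n = 6) in the colonies, a rise of 2.47 ± 0.17 (SE) on the log2 scale with an edgeR adjusted p = 2.06e-06. Zscan4a rose from 20.9 to 115.2 ± 43.2 CPM, and counts of single Zscan4 copies are uncertain. Of 24 primitive endoderm genes 21 rose, 0 fell and 3 did not pass, with 22 risen when adjusted over the list alone. Camera gave an adjusted p of 2.83e-20 (adjusted p = 0.122 with an estimated correlation). Dab2 rose from 32.0 to 184.8 ± 71.5 CPM and Lamb1, a laminin chain, from 201.0 to 893.6 ± 229.1 CPM. Col4a1 (chromosome 8 from 11198423 to 11312826) rose although its chromosome stood higher in ESC. Without chromosomes 8 and Y, 18 of 21 rose. Of 16 trophoblast genes 9 rose, 1 fell (Tfap2c) and 6 did not pass, the same counts as when adjusted over the list alone. By camera the adjusted p was 4.40e-06 (adjusted p = 0.0701 with an estimated correlation). Krt8 rose from 48.8 to 294.4 ± 83.8 CPM.

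Of 36 fibroblast markers 24 rose, 0 fell and 12 did not pass, with 24 risen when adjusted over the list alone. For the list as a whole, the camera adjusted p was 8.23e-20 (adjusted p = 0.0922 with an estimated correlation). Acta2, smooth muscle actin, rose from 108.8 to 317.1 ± 28.7 CPM (SD, n = 6) and Col1a1, a collagen chain of fibroblasts, from 211.7 to 332.3 ± 40.9 CPM. Col1a2 rose from 91.6 to 168.0 ± 19.11 CPM, while Fn1 was 1666 CPM in ESC and 1642 ± 158 CPM in the colonies. These markers stood higher in the colonies beside the primitive endoderm, trophoblast and mesoderm genes. The labels describe feeders and their removal for the colonies and not for the ESC library. Leftover feeders were not tested, and here they cannot be told apart from differentiated cells as a source of these rises. Sparc is in both the fibroblast and the primitive endoderm list. Of 29 mesoderm and endoderm genes 11 rose, 1 fell (Cdx1) and 17 did not pass, while 14 rose and 2 fell when adjusted over the list alone. The camera adjusted p was 0.00115 (adjusted p = 0.0922 with an estimated correlation). Sox17, an endoderm factor, rose from 2.28 to 16.2 ± 5.2 CPM, and Hand1, a factor of extraembryonic and heart mesoderm, from 1.68 to 13.2 ± 2.5 CPM. In limma-voom 6 of the mesoderm and endoderm genes rose.

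Of 8 genes of the Dlk1-Dio3 cluster 3 fell (Meg3, Rian and Mirg), 0 rose and 5 did not pass, with 4 fallen when adjusted over the list alone. Camera gave an adjusted p of 3.93e-05 downward (adjusted p = 0.0786 with an estimated correlation). Meg3 (chromosome 12 from 109541001 to 109571726) fell from 147.8 to 35.8 ± 6.0 CPM (SD, n = 6), by 2.05 ± 0.13 (SE) on the log2 scale, with an edgeR adjusted p = 1.14e-06. Rian (chromosome 12 from 109603940 to 109661716) changed by -3.02 ± 0.17 (SE), with an edgeR adjusted p = 3.61e-07. Mirg fell from 8.05 to 0.890 ± 0.450 CPM. Of 50 other imprinted genes 10 rose, 7 fell and 33 did not pass, while 12 rose and 7 fell when adjusted over the list alone. The camera test did not call this list (adjusted p = 0.0837, and adjusted p = 0.146 with an estimated correlation), and 4 fell without GC colony 2. H19 rose from 31.5 to 151.8 ± 33.0 CPM and Igf2, a growth factor of the same domain, from 0.840 to 11.1 ± 3.2 CPM. Peg10 rose from 195.2 to 539.6 ± 213.9 CPM.

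Of 25 cholesterol synthesis genes 16 rose, 0 fell and 9 did not pass, with 18 risen when adjusted over the list alone. By camera the adjusted p was 8.55e-11 (adjusted p = 0.0922 with an estimated correlation). Idi1, an isomerase of the pathway, rose from 22.8 to 40.5 ± 3.4 CPM (SD, n = 6). Of 34 glycolysis and hypoxia genes 12 fell, 3 rose (P4ha2, P4ha1 and Ier3) and 19 did not pass, while 15 fell and 3 rose when adjusted over the list alone. For the list as a whole, the camera adjusted p was 1.11e-05 downward (adjusted p = 0.314 with an estimated correlation). Gpi1, a glycolytic isomerase, fell from 1589 to 1104 ± 41 CPM, whereas the collagen hydroxylase gene P4ha2 rose from 81.2 to 150.0 ± 18.4 CPM. Of 31 integrated stress response genes 13 fell, 4 rose (Atf3, Stc2, Chac1 and Slc7a1) and 14 did not pass, while 13 fell and 5 rose when adjusted over the list alone. The camera adjusted p was 0.00678 downward (adjusted p = 0.428 with an estimated correlation), and 2 rose without GC colony 2. Asns, asparagine synthetase, fell from 695.8 to 444.2 ± 31.3 CPM. Of 41 interferon response genes 14 rose, 4 fell (Ifitm1, Xaf1, Oas3 and Ifitm3) and 23 did not pass, while 20 rose and 6 fell when adjusted over the list alone. Camera gave an adjusted p of 8.74e-04 (adjusted p = 0.0922 with an estimated correlation). Gbp2, a guanylate-binding protein gene, rose from 4.06 to 18.9 ± 1.8 CPM.

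Of 20 B cell identity genes 1 rose (Irf4), 3 fell (Cd37, Irf8, on chromosome 8, and Vpreb3) and 16 did not pass, while 1 rose and 4 fell when adjusted over the list alone. Camera did not call the list (adjusted p = 0.227, and adjusted p = 0.419 with an estimated correlation). Irf4 was 0.130 CPM in ESC and 2.43 ± 1.10 CPM (SD, n = 6) in the colonies, and limma-voom did not call it. Of 21 GC B cell genes 2 fell (Mef2b, on chromosome 8, and Icam1), 0 rose and 19 did not pass, with 2 fallen when adjusted over the list alone. The camera test did not call the list (adjusted p = 0.243, and adjusted p = 0.428 with an estimated correlation), and its median (-0.14) and mean (0.274) differed in sign. Pax5 was 0.870 CPM in ESC and 0.440 ± 0.290 CPM in the colonies, and Bcl6 5.37 and 4.47 ± 0.81 CPM, without passing the test. Fas (0.940 and 1.71 ± 0.31 CPM) and Cd38 (9.49 and 9.80 ± 1.33 CPM) did not pass either. Of 69 Myc target genes 4 rose (Rrp12, Ddx21, Nolc1 and Utp20), 4 fell (Shmt2, Polr1c, and Mcm5 and Farsa on chromosome 8) and 61 did not pass, while 4 rose and 3 fell when adjusted over the list alone. Camera did not call that list (adjusted p = 0.942, and adjusted p = 0.978 with an estimated correlation), and fry gave the opposite sign. Myc itself rose from 7.14 to 29.6 ± 4.8 CPM, by 2.04 ± 0.17 (SE) on the log2 scale, with an edgeR adjusted p = 9.44e-06.

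**Figure D2:**
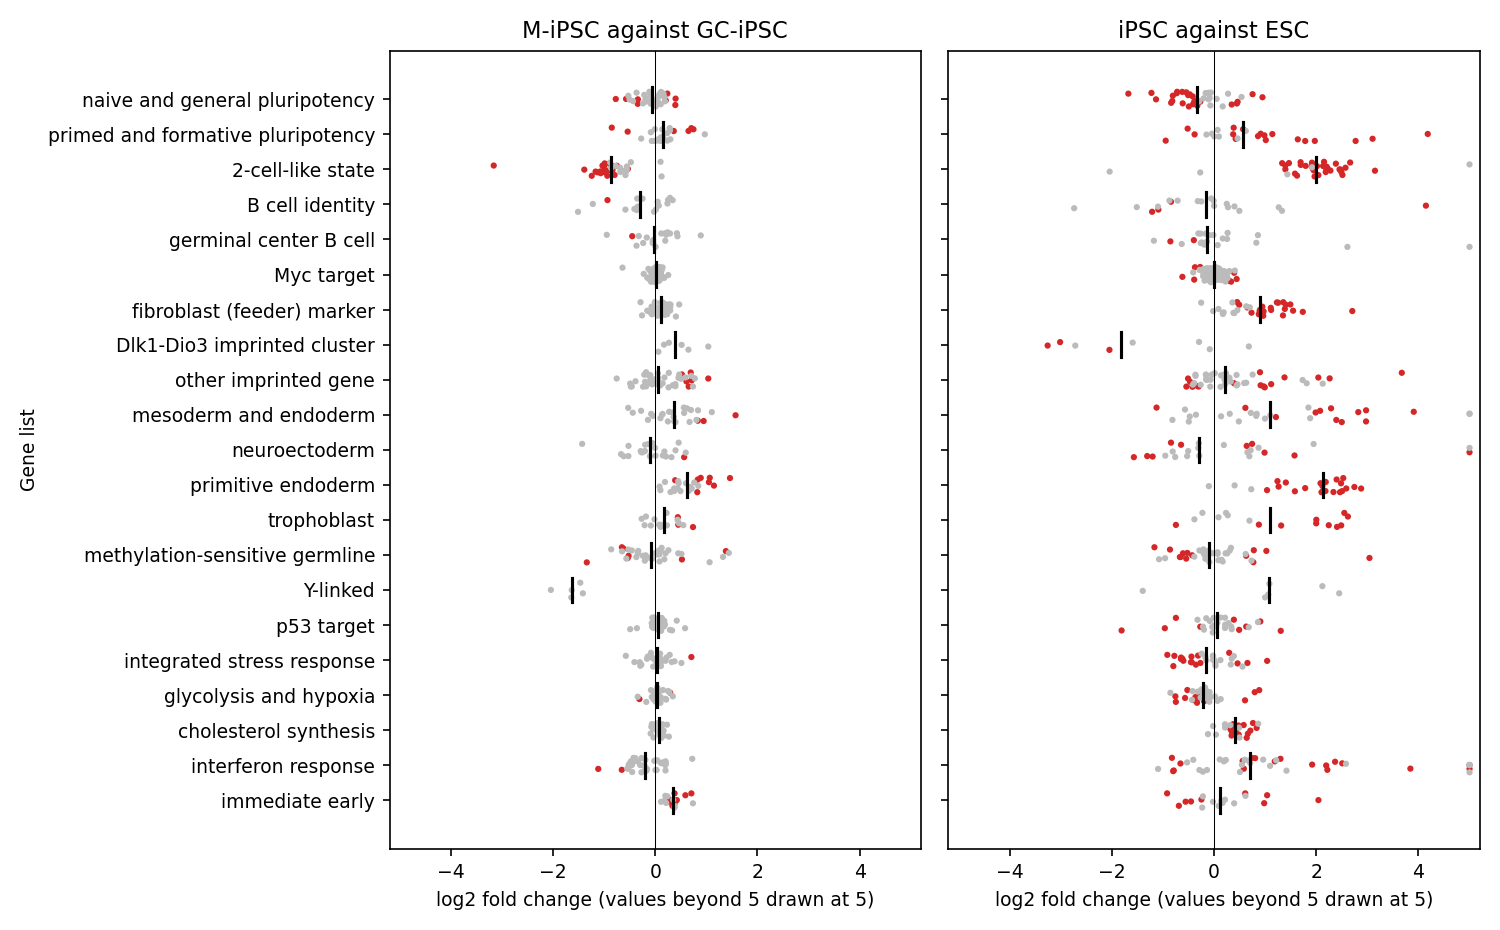
Log2 fold change of each measured member of 21 gene lists, M against GC colonies in the left panel and iPSC colonies against ESC in the right panel: red points passed the adjusted threshold, grey points did not, black bars are list medians, and values beyond 5 are drawn at 5. The 2-cell-like list lies below 0 on the left (median -0.87) and above 0 on the right (median 1.99).

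Among genes outside the lists Csf1r, a macrophage growth factor receptor, had 0 counts in ESC and 3.25 ± 0.76 CPM (SD, n = 6) in the colonies. Rbbp8nl and Olfr881 also had 0 counts in ESC and were 1.64 ± 0.39 and 1.64 ± 0.37 CPM in the colonies, and limma-voom did not call Rbbp8nl. Bmper, a secreted modulator of BMP signals, rose from 0.540 to 9.75 ± 2.88 CPM, by 4.15 ± 0.40 (SE) on the log2 scale, with an edgeR adjusted p = 2.01e-05. Rpl29, a ribosomal protein gene with pseudogene copies, fell from 439.0 to 106.5 ± 9.6 CPM, with an edgeR adjusted p = 5.60e-09. Kank4 fell from 22.4 to 6.23 ± 0.85 CPM. Pmaip1, a member of the p53 target list that encodes the cell death protein Noxa, fell from 182.4 to 52.98 ± 18.4 CPM.

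Each colony group was also set against the ESC library alone. GC colonies differed in 2673 genes (1543 higher, 1130 lower) and M colonies in 3323 genes (1813 higher, 1510 lower) by edgeR; limma-voom gave GC colonies 964 higher and 1124 lower, and M colonies 1254 higher and 1514 lower. The root mean square distance to ESC was 0.907 ± 0.052 log2 units (SD, n = 3) for GC colonies and 0.897 ± 0.034 (SD, n = 3) for M colonies. An exact two-sided permutation test gave p = 0.80, and with a smallest possible p of 0.10 it leaves open whether the distances differ. The sign of the difference turned without GC colony 3 (0.020), without M colony 2 (0.011) and at a mean CPM of at least 10 (0.037).

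Chromosome levels were measured to find gains or losses that would enter the gene calls. The 8 genes of the Y-linked list held 762 counts in ESC, 4804, 3840 and 4388 in GC colonies 1 to 3, and 4371 in M colony 1. M colonies 2 and 3 had 0 counts, which allows up to 0.0904 and 0.0952 CPM. Over all 1570 annotated Y genes they held 50 and 39 counts, against 7860 in M colony 1. By edgeR 0 of 5 tested Y-linked genes passed in M against GC colonies, also when adjusted over the list alone, with 1 lower at an unadjusted p under 0.05, 0 in DESeq2 and 4 lower in limma-voom. By camera the adjusted p was 3.18e-06 downward (adjusted p = 0.181 with an estimated correlation); without M colony 1, 5 of 6 fell, and without M colonies 2 and 3 the list was not called (0.985). Eif2s3y was 65.0 ± 5.7 CPM in GC and 20.9 ± 36.2 CPM in M colonies (SD, n = 3 each), and Ddx3y 44.6 ± 5.1 and 16.7 ± 28.9 CPM. In iPSC colonies against ESC 0 of 6 Y-linked genes passed edgeR, DESeq2 or limma-voom, with 0 at an unadjusted p under 0.05 and 0 when adjusted over the list alone. The camera test did not call that list (adjusted p = 0.340, and adjusted p = 0.771 with an estimated correlation), and its median (1.07) and mean (1.05) lay above 0 while the test pointed down. Without M colony 1, 3 fell there and camera called the list downward (adjusted p = 0.00925), and without M colonies 2 and 3, 4 rose. On chromosome 8 the ESC library had a median log2 ratio of 0.268 over 1039 genes, of which 71.9% were higher in ESC (95% exact Clopper-Pearson interval 69.1% to 74.6%), against 49.5% on other autosomes. The other autosomes of ESC had medians from -0.058 to 0.062, and its X chromosome a median of -0.152 over 748 genes, of which 38% were higher in ESC. Of 310 chromosome 8 genes called in iPSC against ESC, 264 were higher in ESC.

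**Figure D3:**
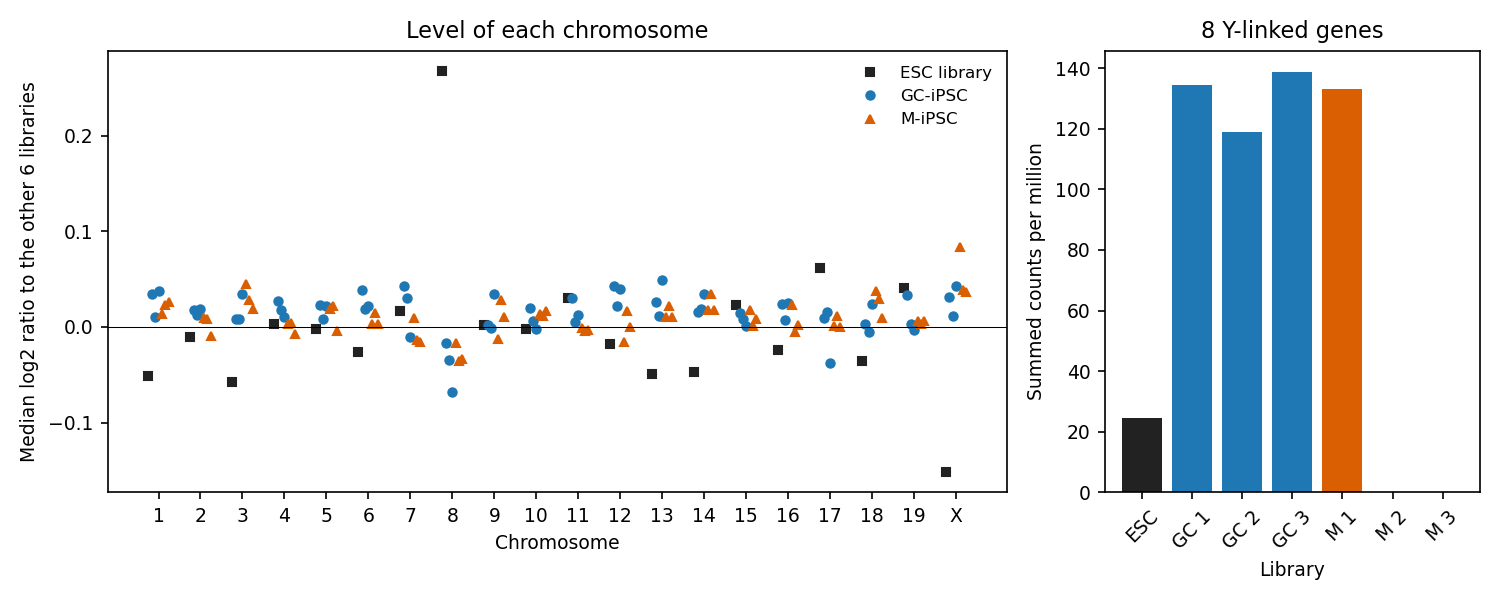
Left, median log2 ratio per chromosome of each library to the other 6 libraries; right, bars with the summed CPM of 8 Y-linked genes in each library. ESC stands at 0.268 on chromosome 8, and M colonies 2 and 3 have no Y-linked bar against 133.2 CPM in M colony 1.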

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

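Both genes here were chosen only after their values were seen. The rule took genes called in opposite directions in GC and M colonies against the ESC library that also passed in M against GC colonies. It gave 2 genes, and their pass in M against GC colonies was a condition of choice, not a further result. Gm27167, on chromosome 8, was 0.70 CPM in ESC, 3.01 CPM in GC colonies (edgeR adjusted p = 0.0197 against ESC) and at 0 counts in M colonies (edgeR adjusted p = 3.60e-04 against ESC), and the difference between the groups passed in M against GC colonies (edgeR adjusted p = 4.17e-05). Tdgf1-ps1, a pseudogene of the pluripotency gene Tdgf1 on chromosome 16, was 66.1 CPM in ESC, 88.6 CPM in GC colonies (edgeR adjusted p = 0.0463 against ESC) and 45.3 CPM in M colonies (edgeR adjusted p = 0.00857 against ESC), and M colonies differed from GC colonies by -0.97 on the log2 scale (edgeR adjusted p = 7.20e-05).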

How the results depend on the processing

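The settings with halved counts, M colonies 2 and 3 left out, chromosomes 8 and Y left out, protein-coding genes alone and both chromosome-level settings were chosen only after the data were seen. The 721 genes of M against GC colonies became 1318 without a count filter, 51 when tested against a fold of 1.5 and 373 without M colonies 2 and 3, and 244 to 814 with 1 colony left out; RLE (721), voom (709), DESeq2 (1077), halved counts (734), the 1 CPM filter (716), all 7 libraries (710) and protein-coding genes (785) stayed within 1.5 times. With the colony number as a block, which no label calls a pair, 963 genes passed, including 710 of the 721. Of its 13 called lists 0 held with an estimated correlation, 8 with fry, 12 with the block and 10 to 13 with 1 colony left out. The lists lost with fry were primitive endoderm (fry adjusted p = 0.1039), Y-linked (0.1039), B cell identity (0.1652), cholesterol synthesis (0.2837) and fibroblast marker (0.5485). Of 12 called lists of iPSC against ESC 0 held with an estimated correlation and 11 with fry. Fry called 14 lists in all there and lost the integrated stress response list. Its 3344 genes ran from 2575 to 3890, those of GC colonies against ESC from 1842 to 3311 and those of M colonies against ESC from 2416 to 3935. The difference in distance to ESC (-0.009) ran from -0.025 to 0.020 with 1 colony left out and was 0.037 at a mean CPM of at least 10. The chromosome 8 level of ESC (0.268) was 0.306 at that CPM. For single genes, 2798 values kept direction and side, 214 fell short of the threshold, 31 crossed it and 25 turned sign. Log2 changes that turned in M against GC colonies without M colonies 2 and 3 were Esrrb -0.141, Ldha -0.002, Ddx3y 0.167, Mdm2 -0.044, Srebf2 -0.007 and Hmgcs1 -0.010. With protein-coding genes alone they were Ldha -0.001, Fn1 -0.003 and Hmgcs1 -0.001, and with the 1 CPM filter Fn1 -0.003. With 1 colony left out Esrrb ran from -0.026 to 0.141, Ldha from -0.042 to 0.055, Fn1 from -0.084 to 0.115, Ccng1 from -0.050 to 0.035 and Hmgcs1 from -0.012 to 0.026. In iPSC against ESC, Eif2s3y was -0.75 and Ddx3y -2.01 with voom, and with 1 colony left out they ran from -3.75 to 2.75 and from -4.96 to 1.38, lowest without M colony 1, the M colony with Y-linked RNA. None of these genes had passed the test in the comparison where it turned. Apart from leaving out samples or genes, the cause was not tested.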

Other observations

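The tests of shared pseudogene reads, of Y chromosome loss as the whole cause, of female origin and of shallower sequencing were chosen only after the result was seen, as were the named genes outside the rule. Of 36 methylation-sensitive germline genes, which DNA methylation keeps silent in somatic cells, 2 rose (Tex15 and Ddx4) and 5 fell (Smc1b, Stra8, Tex19.2, Tdrd12 and Fkbp6) in M against GC colonies and 29 did not pass, while 5 rose and 9 fell when adjusted over the list alone. Camera did not call the list (adjusted p = 0.144, and adjusted p = 0.344 with an estimated correlation). Tex15 went from 5.95 ± 1.14 to 15.5 ± 5.2 CPM (SD, n = 3 each). The number that fell was 0 without GC colony 2 or M colony 3, 1 without GC colony 1, 2 without M colony 2 and 8 without M colony 1, and Ddx4 was lost without GC colony 2, M colony 2 or M colony 3 (edgeR adjusted p up to 0.102). In iPSC colonies against ESC 5 of 36 rose (Rhox5, Mael, Taf7l, Rpl10l and Sycp1), 8 fell and 23 did not pass, while 6 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.312, and adjusted p = 0.428 with an estimated correlation). Rhox5, an X-linked homeobox gene, was 11.9 CPM in ESC and 98.5 ± 17.9 CPM (SD, n = 6) in the colonies. Of 23 neuroectoderm genes 1 rose in M colonies (Sox11, from 35.04 ± 2.27 to 51.9 ± 3.0 CPM), 0 fell and 22 did not pass, with 1 risen when adjusted over the list alone (camera adjusted p = 0.859, and adjusted p = 0.905 with an estimated correlation). Against ESC 5 of 25 rose (Sox11 and Gbx2 among them), 5 fell (Sox1, Tubb3, Pax6, Lhx2 and Sox21; the first 2 lie on chromosome 8) and 15 did not pass, while 7 rose and 7 fell when adjusted over the list alone. That list was not called (camera adjusted p = 0.589, and adjusted p = 0.830 with an estimated correlation), its median (-0.291) and mean (0.436) differed in sign, and 3 rose without GC colony 1, GC colony 2 or M colony 3.

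Of 30 p53 target genes 0 passed in M against GC colonies by edgeR or limma-voom or when adjusted over the list alone, 1 rose by DESeq2 and 4 were higher at an unadjusted p under 0.05. The list was not called (camera adjusted p = 0.0895, and adjusted p = 0.615 with an estimated correlation) except without M colony 1 (0.00365), when 1 rose. Ccng1 was 270.7 ± 13.6 CPM in GC colonies and 268.4 ± 12.8 CPM in M colonies (SD, n = 3 each). Against ESC 5 rose (Plk2, Ccng1, Cd80, Ano3 and Ercc5), 4 fell (Pmaip1, Fdxr, Rrm2b and Ei24) and 21 did not pass, while 6 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.559, and adjusted p = 0.838 with an estimated correlation). In M against GC colonies 1 of 31 integrated stress response genes rose (Atf3, from 63.4 ± 6.4 to 103.4 ± 27.0 CPM), 0 fell and 30 did not pass, while 5 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.234, and adjusted p = 0.754 with an estimated correlation). Atf3 was lost without GC colony 2, M colony 1 or M colony 3 (edgeR adjusted p up to 0.119), and without GC colony 2 the list was called upward (0.0221) with 0 genes past the threshold. Of 34 glycolysis and hypoxia genes 1 rose (Egln1, an oxygen sensor, from 123.0 ± 7.8 to 150.5 ± 4.6 CPM), 1 fell (Pfkp) and 32 did not pass, the same counts as when adjusted over the list alone (camera adjusted p = 0.133, and adjusted p = 0.732 with an estimated correlation). That list was called upward without GC colony 1 (0.0240) and without M colony 1 (9.65e-04), Egln1 was lost without GC colony 2, M colony 1 or M colony 3 (edgeR adjusted p up to 0.176), and Pfkp was lost in each leave-out but that of M colony 2 (up to 0.247). Of 25 cholesterol synthesis genes 0 passed by edgeR or limma-voom or when adjusted over the list alone, 2 rose by DESeq2 and 3 were higher at an unadjusted p under 0.05. Camera called the list upward (adjusted p = 0.0254, and adjusted p = 0.520 with an estimated correlation), a call that ended without GC colony 2 (0.0718), M colony 3 (0.216) or M colonies 2 and 3 (0.985), and 1 gene rose without GC colony 3. Srebf2 was 367.9 ± 18.5 and 400.6 ± 30.4 CPM. Of 18 immediate early genes 4 rose (Myc, Jun, Ier5 and Atf3), 5 fell (Fos, Egr1, Ier2, Egr2 and Dusp1) and 9 did not pass in iPSC colonies against ESC, while 4 rose and 7 fell when adjusted over the list alone. Camera did not call that list (adjusted p = 0.871, and adjusted p = 0.947 with an estimated correlation), fry gave the opposite sign, and 3 fell without GC colony 2 or M colony 3. Fos fell from 1083 CPM to 573.5 ± 65.7 CPM (SD, n = 6).

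Some genes outside the rule that differed between the colony groups were chosen after their values were seen. Gm42047, a noncoding RNA gene on chromosome 8 from 121833247 to 121841178, was 397.6 CPM in ESC, 0.020 ± 0.030 CPM in GC colonies and 348.8 ± 6.4 CPM in M colonies (SD, n = 3 each). Rps3a1, the protein-coding gene beside the Rps3a3 pseudogene in name, was 1050 ± 24 CPM in GC colonies and 1637 ± 52 CPM in M colonies. Rps3a2, a pseudogene that the rule did name, fell from 104.2 ± 9.7 to 20.85 ± 3.77 CPM, in the direction of Rps3a3. Rpl34 likewise was 156.6 ± 14.3 and 270.7 ± 12.7 CPM, and its pseudogene Rpl34-ps1 88.1 ± 6.4 and 47.65 ± 2.09 CPM. Whether reads were assigned differently between these genes and their copies was not tested. Gm15247, an antisense RNA within Mid1, was 8.86 ± 1.07 and 0.190 ± 0.090 CPM. Gm18363, a processed pseudogene, was 9.31 ± 1.36 CPM in GC colonies and at 0 counts in M colonies.

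The 721 genes called between M and GC colonies could come from the sorted cell state, which was not tested apart from the donor, or from other differences. Loss of the Y chromosome as the whole cause is argued against only by 1 library, M colony 1, which has Y-linked RNA. For 480 of 695 genes off the Y chromosome it lay nearer the mean of M colonies 2 and 3 than the GC mean. The exact 95% interval of 65.5% to 72.5% takes genes as independent, which they are not, so it is too narrow. Loss of the Y chromosome as part of the cause cannot be told apart, because the share of 69.1% met neither bound set in advance. Linked donor genotype stays open as a candidate explanation for part of the calls: called genes were neighbours in 76 pairs, against a mean of 28.4 and at most 49 in 10000 shuffles, and in 39 pairs among protein-coding genes outside the lists, against at most 38. Neighbouring calls also exceeded their shuffled mean in iPSC colonies against ESC among protein-coding genes outside the lists and off chromosome 8 (521 pairs against 439.7). The ESC line may itself differ in genotype from the donors, so that excess cannot separate genotype from coregulated genes. Clustered gene families may add to the 76 pairs. On chromosome 12, 14 called genes lay from 85000001 to 90000000. On chromosome 7, 8 called Zscan4 genes or pseudogenes lay from 10000001 to 15000000. Other windows rich in calls held genes of unrelated names. On chromosome X from 140000001 to 145000000, 6 of 23 tested genes were called, Irs4 and Prps1 among them. On chromosome 14 from 70000001 to 75000000, 7 of 36 were called, Bmp1 and Itm2b among them. Reads shared with processed pseudogenes cannot be told apart as a cause: 92.5% of the calls were neither pseudogenes nor ribosomal protein genes, but so were 89.6% of all tested genes, and other parent genes of pseudogenes were not identified.

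The 10 splits of the 6 colonies into groups of 3 are too few for a share under 0.05. The real split was the 1 of 10 with the most genes (721, highest other 0 by edgeR) and the 1 of 10 with the most lists (13, highest other 7). Every other split mixes GC and M colonies in both groups, so any difference between them adds to the spread within groups and lowers the gene count. The 0 genes of the other splits are therefore no separate support for the 721.

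The ESC library stood higher over chromosome 8. A few abundant genes are argued against, because 71.9% of 1039 chromosome 8 genes were higher in ESC, against 49.5% on other autosomes. An extra chromosome 8 in part of the cells is a candidate explanation: 4 segments of the chromosome with equal numbers of genes all had medians above 0, up to 0.334. If RNA scaled exactly with copy number, 1 extra copy in 40.8% of cells would give the median of 0.268. That share is not a fixed estimate, since the median was 0.306 at a mean CPM of at least 10 and differed between segments. A gain of only part of the chromosome cannot be told apart, because the lowest segment had a median of 0.114, between the bounds set in advance. Apart from these gains no biological explanation was tested, since the design gives none for a single library.

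M colonies 2 and 3 had no counts of the 8 Y-linked genes. Cells of a female origin with a second active X are argued against, because X-linked genes had a median log2 ratio of at most 0.039 in these colonies, against 0.084 in M colony 1. Female cells with a single active X would give a similar ratio, so this test cannot exclude them. For that case only the labels, by which the mice were male, speak against a female origin. Shallower sequencing is argued against, because at the rate of M colony 1 at least 4198 counts would have been seen. Loss of the Y chromosome from these colonies may remain as a hypothesis that RNA alone leaves untested.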
